A study of Homo sapiens with 254 samples.

How the data were processed

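The series measured polyadenylated RNA in single cells and single nuclei of KD3, an established immortalized human myoblast line. Per the labels, proliferating myoblasts were kept in serum-containing growth medium, and differentiation was induced in a low-serum medium with an insulin, transferrin and selenium supplement. Myotubes and mononucleated cells (MNCs) were harvested 72 h after induction. Nuclei were released with a mild detergent. Cells and nuclei were captured on a microfluidic system, and full-length cDNA was amplified from each and sequenced without molecular identifiers and without strand information.

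The authors aligned reads to GRCh38 with STAR 2.4.2a and quantified genes with RSEM 1.2.12, per the submitters' processing notes. The annotation release they used is not given in the sources used here. The deposited gene tables hold expected counts in one set of files and TPM in the other, over 36161 genes and 208 libraries. Both deposited units carry an added constant of 0.1 in every value, which was subtracted before use. After subtraction, 92.0% of the nonzero expected counts were whole numbers within 0.011, and the expected counts were rounded to whole numbers. The other 8 of the 10 deposited tables are subsets of the full ones in libraries and genes, and no value in them differed from the full tables. Gene positions were taken from GENCODE release 29, in which 35462 of the gene identifiers were found.

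The labels list 254 samples, of which 208 matched a column of values. The other 46 samples (5 myoblast nuclei, 35 MNC nuclei and 6 myotube nuclei) had no column and were not analysed here. Columns named as myocytes were taken as the MNC nuclei, because MNC is the only differentiated label other than myotube and each of the 35 wells exists among the MNC wells of the labels. The comparisons, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The labels name no separate cultures, so each group was treated as 1 sample. Nuclei of 1 culture are not replicates of a culture, and no test between groups was made, no standard error was given and no changed genes were counted.

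For each group the counts were summed over its libraries and divided by the group's total gene counts to give CPM. Ratios are given as fold or log2, and log2 ratios have a constant of 0.5 added to each summed count. Intervals are exact 95% Poisson intervals for sums and their ratios and exact Clopper-Pearson 95% intervals for shares. Amplified reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A group with no read of a gene was given a floor of 3 counts over the group, and folds against it are lower bounds. For a gene with no read in any library of a group, the share of libraries with a read that this allows was set at 3 divided by the number of libraries, not from a Clopper-Pearson interval, and is up to 4.0% for the myoblast cells, 5.56% for the myoblast nuclei, 8.57% for the MNC nuclei and 6.82% for the myotube nuclei. Numbers of genes with a read were compared after each library was thinned at random to 430000 reads, which left out 2 myoblast cells, 6 myoblast nuclei, 1 MNC nucleus and 11 myotube nuclei that were shallower.

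The 22 gene lists were sarcomere, excitation-contraction coupling and synapse, fusion and adhesion, muscle metabolism, myogenic regulators, inhibitors of myogenesis, cell cycle, cell cycle exit, mesenchymal matrix, smooth muscle, quiescence and reserve cells, IGF axis, early response and stress, bone and cartilage markers, endothelial and immune markers, adipocyte markers, mitochondrially encoded genes, ribosomal proteins, abundant cytosolic mRNAs, nuclear lncRNAs, snoRNA host lncRNAs and microRNA host lncRNAs. Of their 523 symbols, 504 were found. A member counted as measured with at least 20 summed reads in either group, and a list with fewer than 5 measured members was given no median. Each median has an exact order-statistic 95% interval over its members, which are not independent, and a percentile among the medians of 10000 random lists of the same size drawn from 20 bins of expression.

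Named genes followed a rule. Its first part took, in each direction, the 8 protein-coding genes and the 4 lncRNA genes with the largest log2 ratio among genes at 20 CPM or more and with a read in at least 25% of libraries in the higher group, and at least 4-fold apart by mean CPM. Its second part took from each list with at least 5 measured members the 2 members farthest in the direction of the list and the 1 farthest against it. Its last part named MYOD1, MYOG, MYF5, PAX7, MKI67, MYH3, CKM, ID3, COL1A1 and MALAT1. Not all genes so named are printed, and a gene outside the rule is said to have been chosen after its values were seen. The tables hold 2 entries with the symbol MALAT1, and the name is used here for the lncRNA ENSG00000251562. The other entry, ENSG00000279576, is annotated as protein-coding.

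Correlations between nuclei were Spearman coefficients of log2(CPM + 1) across 9089 genes for all pairs within a group after thinning. Alternatives covered the scaling of the totals (TMM from edgeR 4.0.16 in R 4.3.3, totals without mitochondrially encoded genes and without the 20 genes with the most reads), equal weights for libraries, the authors' TPM, thinning, the constant, filters on genes and libraries, a threshold of 5 reads for a share of libraries, the libraries in the authors' smaller tables, and leaving out the library with the most reads in each group. All other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No doublet caller and no clustering was run. The steps were tested on simulated data in which 50 genes of 9370 were set to each fold. The log2 ratio, taken relative to the median over the simulated genes, was recovered within 1 for 98.0% of the genes set to 4-fold. It was so recovered for 100% of those set to 2-fold, 8-fold or 0.125-fold. The simulated genes were well above the minimum of 20 summed reads, and their reads were spread over the libraries. The check therefore does not cover genes near that minimum or genes with most reads in 1 library.

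Reads of opposite strands at one locus cannot be told apart here, so values of antisense genes can include reads of the partner gene. The 3 lincRNA genes of one cluster, CH507-513H4.3, CH507-513H4.4 and CH507-513H4.6, had near-equal counts in each library (r of at least 0.99), and values of near-identical genes such as these rest on reads that the quantification divides between them.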

Results

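KD3, an immortalized human myoblast line, was profiled by full-length single-cell and single-nucleus RNA sequencing at 3 stages of differentiation. Proliferating myoblasts were sequenced both as 75 whole cells and as 54 nuclei. After 72 h in differentiation medium, 44 nuclei of multinucleated myotubes and 35 nuclei of mononucleated cells (MNCs) were sequenced. Gene counts per library had a median of 1103626 in myoblast cells (range 207810 to 2089015) and 626248.5 in myoblast nuclei (304577 to 934845). They had a median of 2010234 in MNC nuclei (412269 to 4619198) and 551021 in myotube nuclei (109775 to 940245). The median number of genes with a read at 430000 reads per library was 7203 in myoblast cells, 4908.5 in myoblast nuclei, 3258 in MNC nuclei and 2815 in myotube nuclei. Each group is 1 sample, so values below carry counting error only, and no difference between groups was tested. Levels are given in CPM, the counts summed over a group's libraries and scaled to their total, and the interval after a value is its exact 95% counting interval.

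Myoblast nuclei were compared with whole myoblasts, which shows what part of the cell's RNA the nucleus libraries hold. RNA of the mitochondrial genome, which codes for subunits of the respiratory chain, took a larger share of reads in nuclei than in cells. Messages of ribosomal proteins and other abundant cytosolic proteins were lower in nuclei, and long noncoding RNAs (lncRNAs) took a larger share there. Most cell cycle genes were within 2-fold of each other in the 2 preparations, and no read of MYOG, a transcription factor of terminal muscle differentiation, was found in either.

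Mitochondrially encoded genes made up 37.29% of gene counts in myoblast nuclei (Clopper-Pearson interval 37.27% to 37.3%) and 4.586% in myoblast cells (4.581% to 4.59%), a ratio of 8.13. The median per library was 40.5% in nuclei and 4.2% in cells. All 13 mitochondrially encoded genes were at least 2-fold higher in nuclei, with a list median log2 ratio of 3.15 (interval 2.51 to 3.28). MT-ND1 (ENSG00000198888, mitochondrial genome, 3307 to 4262), a subunit of respiratory complex I, stood at 18010 CPM in nuclei and 1836 CPM in cells, 9.81-fold higher (9.75 to 9.87). LncRNA genes made up 7.41% of counts in nuclei and 2.783% in cells, a ratio of 2.66. Without the 3 near-identical CH507-513H4 lincRNA genes the shares were 4.348% and 2.618%, a log2 ratio of 0.73 where the ratio with them was 1.41.

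**Figure D1:**
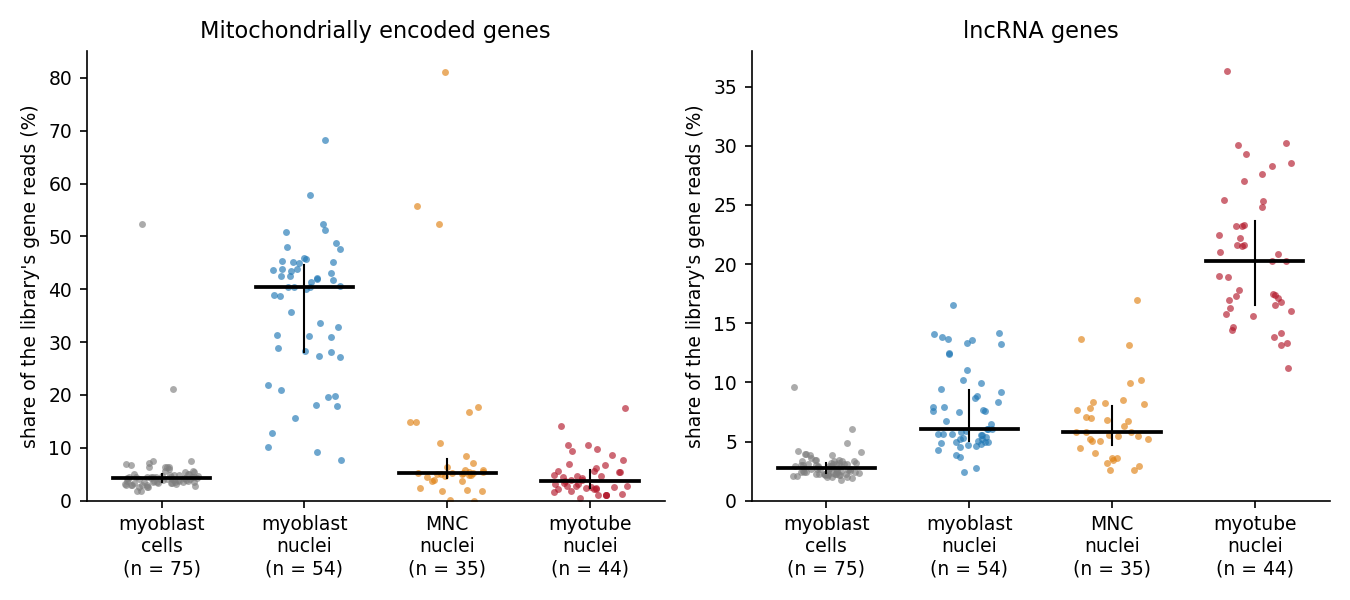
Share of gene counts (percent) from mitochondrially encoded genes and from lncRNA genes, one point per library, for the 75 myoblast cells, 54 myoblast nuclei, 35 MNC nuclei and 44 myotube nuclei; the horizontal line is the median and the vertical line spans the quartiles. The median mitochondrially encoded share was 40.5% in myoblast nuclei and 4.2% in myoblast cells, and the median lncRNA share was 20.2% in myotube nuclei and 6.05% in myoblast nuclei.

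Ribosomal protein messages had a median log2 ratio of −1.83 (−1.97 to −1.70) in nuclei over cells, and 74 of 78 were at least 2-fold lower. None of the 10000 random lists had a lower median. RPL15, a protein of the large ribosomal subunit, stood at 338.5 CPM in nuclei and 2495 CPM in cells, 7.37-fold lower (7.23 to 7.51), and RPS25 was 6.14-fold lower (5.97 to 6.32). Of the abundant cytosolic messages, 21 of 25 were at least 2-fold lower, with a median of −1.77 (−2.11 to −1.58). FTL, the ferritin light chain, was 19.0-fold lower (18.6 to 19.4). FTH1, the ferritin heavy chain, stood at 147 CPM in nuclei and 2017 CPM in cells, and at 1004 CPM in cells without cell replicate 66, which held 51.5% of its reads. Of the snoRNA host lncRNAs, whose spliced transcripts are exported and decay in the cytoplasm, 7 of 13 were at least 2-fold lower on total counts. None was at least 2-fold higher on total counts (median −1.01). Leaving mitochondrially encoded genes out of the totals raised the median over all genes by 0.60, so counts of genes near 2-fold depend on the scaling. SNHG8 stood at 0.818 CPM with reads in 11 of 54 nuclei and at 31.6 CPM with reads in 63 of 75 cells.

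Among lncRNAs known to stay in the nucleus, 6 of 16 were at least 2-fold higher in nuclei and 1 was lower, with a median of 0.74 (−0.10 to 1.78). MALAT1 (ENSG00000251562, chromosome 11, 65497688 to 65506516), a nuclear speckle lncRNA, stood at 8134 CPM in nuclei and 5222 CPM in cells, 1.56-fold higher. Among microRNA host transcripts, 9 of 19 were at least 2-fold higher and 4 lower, with a median of 0.33. MIR503HG was 13.4-fold higher (12.4 to 14.5), with reads in 49 of 54 nuclei and 46 of 75 cells. MIRLET7BHG, which gives rise to members of the let-7 family, was 13.7-fold higher (12.4 to 15.1), with reads in 48 of 54 nuclei and 43 of 75 cells. The lncRNA RP5-940J5.9 was 49.3-fold higher (45.5 to 53.5), with reads in 53 of 54 nuclei and 26 of 75 cells, though reads of its antisense partner could not be told apart from its own.

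On total counts, 26 of the 42 cell cycle genes were within 2-fold, 11 were lower and 5 were higher in nuclei. Their median was −0.26 (−0.60 to 0.17) on total counts and turned to 0.35 when mitochondrially encoded genes were left out of the totals. That scaling raised the median over all genes by 0.60, so the counts of lower and higher genes also depend on it. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), a marker of cycling cells, stood at 476 CPM with reads in 53 of 54 nuclei and at 423 CPM with reads in 57 of 75 cells. BIRC5, a component of the chromosomal passenger complex, was 3.59-fold lower and CDT1, a replication licensing factor, 6.38-fold higher in nuclei. MYF5 (ENSG00000111049, chromosome 12, 80716912 to 80719673), a transcription factor of committed myoblasts, stood at 73.6 CPM with reads in 48 of 54 nuclei and at 834 CPM with reads in 73 of 75 cells, 11.3-fold lower (10.9 to 11.8). HES1, a transcriptional repressor downstream of Notch, was 58.4-fold lower (33.4 to 113), with reads in 7 of 54 nuclei and 62 of 75 cells. SDC4, a heparan sulfate proteoglycan, was 8.47-fold lower (8.03 to 8.94), and the laminin receptor subunit ITGA7 was 7.59-fold higher (6.75 to 8.56).

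Some single genes were far apart between the preparations, in both directions. TMEM14A had reads in 61 of 75 cells and 1 of 54 nuclei (203-fold lower, 79.3 to 747), the latter being myoblast nucleus replicate 13. LSM10, a component of the histone pre-mRNA processing particle, was 176-fold lower, with reads in 56 of 75 cells and 3 of 54 nuclei, at 0.151 CPM in nuclei and 0.0614 CPM without myoblast nucleus replicate 16. ATG16L2, which binds an autophagy conjugate, stood at 32.6 CPM with reads in 21 of 54 nuclei and at 0.312 CPM with reads in 11 of 75 cells. The DNA helicase PIF1 was 82.1-fold higher in nuclei, with reads in 23 of 54 nuclei and 10 of 75 cells. Of the 22 measured sarcomere genes, 15 were at least 2-fold lower in nuclei and 2 higher, with a median of −1.90 (−5.49 to −0.33). MYOG and PAX7, a marker of muscle stem cells, had no read in the 75 cells or the 54 nuclei, which allows shares of up to 4.0% and 5.56%. The median over 16137 genes was −0.31 on total counts and moved by 0.67 when mitochondrially encoded genes and the 20 genes with the most reads were left out. Relative to it the ribosomal protein median was −1.52, and with those totals that list's own median was −1.16.

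Myotube nuclei were compared with myoblast nuclei, which shows the RNA of nuclei after fusion and terminal differentiation. Most sarcomere genes and most genes of excitation-contraction coupling and the synapse were higher in myotube nuclei, and TNNI1, TNNT1 and RYR1 had reads in most of them and in none of the 54 myoblast nuclei. Most cell cycle genes were lower in myotube nuclei, and each of the 42 had reads in a smaller share of nuclei. LncRNA genes took a larger share of reads in myotube nuclei, and MALAT1 and COL1A1 were higher there.

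Of the 35 measured sarcomere genes, 32 were at least 2-fold higher in myotube nuclei and 1 was lower. The list median log2 ratio was 8.99 (7.49 to 10.28), or 7.38 with genes without a read at their floor, and lay above the medians of all 10000 random lists. TNNI1 (ENSG00000159173, chromosome 1, 201403768 to 201429866), the slow skeletal troponin I, had reads in 39 of 44 myotube nuclei (88.6%, 75.4% to 96.2%) at 327 CPM (320 to 335). No read was found in 54 myoblast nuclei, so it was at least 3600-fold higher. TNNT1, the slow skeletal troponin T, had reads in 37 of 44 nuclei and was at least 1780-fold higher. MYH3 (ENSG00000109063, chromosome 17, 10628526 to 10657309), the embryonic myosin heavy chain, had reads in 33 of 44 nuclei (75.0%, 59.7% to 86.8%) at 160.5 CPM. It had reads in 2 of 54 myoblast nuclei, at 0.363 CPM and at 0.123 CPM without myoblast nucleus replicate 35. MYPN, a binding partner of titin, went the other way, at 11.7 CPM in myotube nuclei and 30.4 CPM in myoblast nuclei (17.9 CPM without myoblast nucleus replicate 41).

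Of the 23 measured genes of excitation-contraction coupling and the synapse, 20 were at least 2-fold higher in myotube nuclei, with a median of 4.99 (1.66 to 8.95; 3.84 with genes at their floor). RYR1 (ENSG00000196218, chromosome 19, 38433699 to 38587564), the calcium release channel of the sarcoplasmic reticulum, had reads in 36 of 44 myotube nuclei (81.8%, 67.3% to 91.8%) at 695 CPM (684 to 706). It had no read in myoblast nuclei and was at least 7650-fold higher. CHRNB1, a subunit of the muscle acetylcholine receptor, was 2.58-fold lower, at 58.9 CPM (37.4 CPM without myotube nucleus replicate 6). Muscle metabolism genes had a median of 3.56 (−0.42 to 7.43), with 10 of 13 at least 2-fold higher. The muscle creatine kinase CKM, one of them, had reads in 8 of 44 nuclei, and its 33.9 CPM was 3.82 CPM without myotube nucleus replicate 40.

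Myogenic regulators had a median of 1.67 (0.87 to 4.57), with 11 of 16 at least 2-fold higher and 2 lower in myotube nuclei. MYOG (ENSG00000122180, chromosome 1, 203083132 to 203086036) had reads in 24 of 44 myotube nuclei (54.5%, 38.9% to 69.6%) and in 15 of 33 (45.5%) at equal depth. Its level was 46.4 CPM (43.6 to 49.2), at least 510-fold higher than in the 54 myoblast nuclei, none of which had a read. MYOD1 (chromosome 11, 17719568 to 17722131), which commits cells to the muscle lineage, had reads in 18 of 44 myotube nuclei and 5 of 54 myoblast nuclei. Its level in myotube nuclei was 21.2 CPM, and 9.04 CPM without myotube nucleus replicate 21. Its level in myoblast nuclei was 0.878 CPM, and 0.524 CPM without myoblast nucleus replicate 9. MYF5 had reads in 10 of 44 myotube nuclei at 149 CPM, of which myotube nucleus replicate 15 held 97.7%, and the level without it was 3.55 CPM against 73.6 CPM in myoblast nuclei. CDKN1C, an inhibitor of cyclin-dependent kinases, had reads in 24 of 44 myotube nuclei and 2 of 54 myoblast nuclei, 374-fold higher (172 to 1020). Its level in myoblast nuclei was 0.182 CPM and 0.0928 CPM without myoblast nucleus replicate 38.

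**Figure D2:**
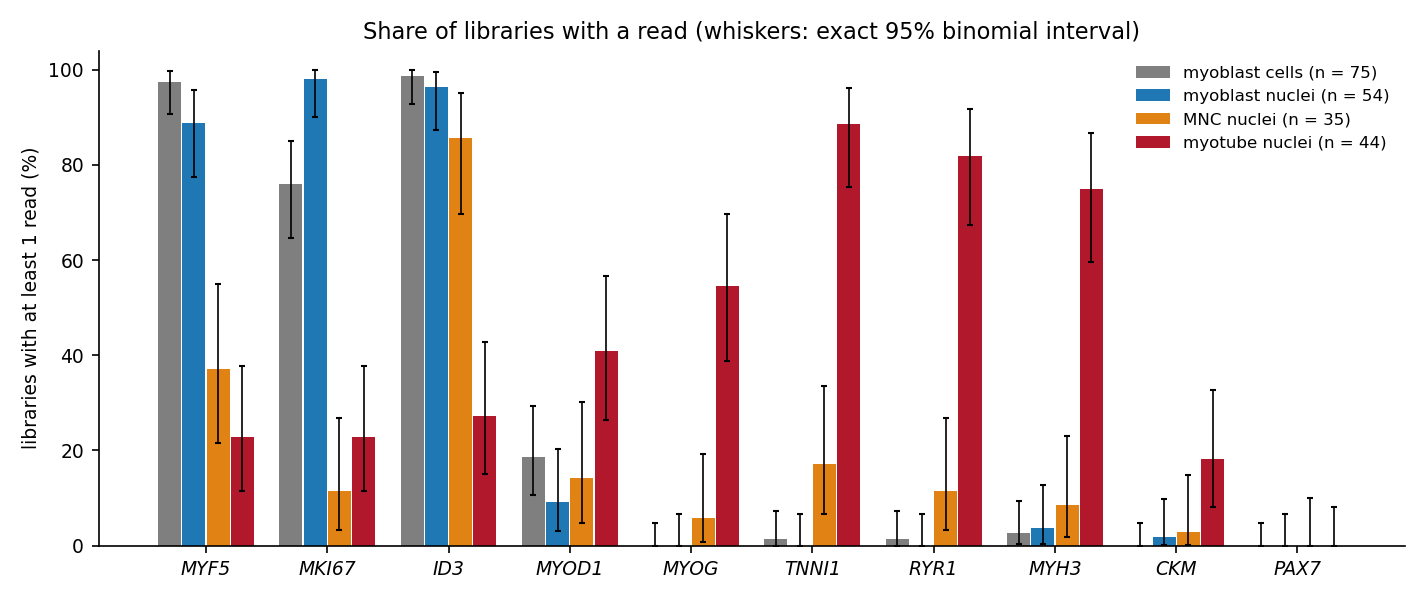
Share of libraries (percent) with at least 1 read of MYF5, MKI67, ID3, MYOD1, MYOG, TNNI1, RYR1, MYH3, CKM and PAX7 in the 4 groups. Libraries were not thinned to equal depth. Bars are shares and whiskers exact 95% binomial intervals. MYOG reads were found in 54.5% of myotube nuclei and 5.71% of MNC nuclei and in none of the 54 myoblast nuclei.

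Cell cycle genes had a median of −3.85 (−4.85 to −2.69), or −4.09 relative to all genes. Of the 42 genes, 36 were at least 2-fold lower and none was at least 2-fold higher, and no random list had a lower median. NUF2 (ENSG00000143228, chromosome 1, 163266576 to 163355764), a kinetochore protein, had reads in 43 of 54 myoblast nuclei and none of 44 myotube nuclei, at least 989-fold lower. CDC20, an activator of the anaphase-promoting complex, had reads in 37 of 54 myoblast nuclei and 1 of 44 myotube nuclei. MKI67 had reads in 53 of 54 myoblast nuclei and 10 of 44 myotube nuclei, at 476 CPM and 251 CPM, of which myotube nucleus replicate 13 held 74.3%, and 66.7 CPM without it. AURKA, a mitotic kinase, stood at 87.7 CPM in myotube nuclei, and at 3.50 CPM without myotube nucleus replicate 31, against 83.9 CPM in myoblast nuclei. IRS2, a substrate of the insulin receptor, was 30.5-fold lower (23.7 to 40.0), with reads in 11 of 44 myotube nuclei and 45 of 54 myoblast nuclei.

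LncRNA genes made up 20.11% of counts in myotube nuclei (20.1% to 20.13%), 2.71-fold the share in myoblast nuclei. Of the nuclear lncRNAs, 9 of 16 were at least 2-fold higher and 1 was lower, with a median of 1.39 (0.34 to 2.82), while 9 had reads in a smaller share of myotube nuclei and 5 in a larger one. MALAT1 stood at 57400 CPM, 7.06-fold higher (7.03 to 7.09). KCNQ1OT1 (ENSG00000269821, chromosome 11, 2608328 to 2699994), the antisense lncRNA of an imprinted domain, stood at 1937 CPM and 113 CPM, 17.2-fold higher (16.6 to 17.8), with reads in 42 of 44 and 45 of 54 nuclei. MIR143HG, the host of a microRNA of contractile cells, had reads in 19 of 44 myotube nuclei at 178 CPM and in 1 of 54 myoblast nuclei. All but 1 of the 13 mitochondrially encoded genes were at least 2-fold lower in myotube nuclei, with a median of −2.96.

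COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632), the main chain of type I collagen, stood at 14250 CPM in myotube nuclei and 1961 CPM in myoblast nuclei, 7.27-fold higher (7.21 to 7.33), with reads in 44 of 44 and 54 of 54 nuclei. The mesenchymal matrix list went both ways, with 12 of 40 members at least 2-fold higher and 10 lower, and its median of 0.53 (−0.55 to 0.99) turned to −0.08 when mitochondrially encoded genes were left out of the totals. APOE (ENSG00000130203, chromosome 19, 44905754 to 44909393), a lipid carrier, had reads in 32 of 44 myotube nuclei at 309 CPM and none in 54 myoblast nuclei, at least 3410-fold higher. NPNT, an integrin ligand of the matrix, had reads in 30 of 44 myotube nuclei and was at least 3190-fold higher.

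Inhibitors of myogenesis had a median of 1.475, with 10 of 17 at least 2-fold higher and 5 lower in myotube nuclei on total counts. These counts depend on the scaling, since leaving mitochondrially encoded genes out of the totals moved the median over all genes by −0.61. NOTCH3 (ENSG00000074181, chromosome 19, 15159038 to 15200981), a receptor of the Notch pathway, had reads in 40 of 44 myotube nuclei at 437 CPM and in 2 of 54 myoblast nuclei at 3.30 CPM, 132-fold higher (110 to 161). Without myoblast nucleus replicate 9, which held 98.2% of its reads there, the level in myoblast nuclei was 0.0616 CPM. The remaining medians were 0.84 for fusion and adhesion, 0.85 for cell cycle exit, −0.02 for quiescence and reserve cells, −0.46 for early response and stress, −0.36 for abundant cytosolic messages, −0.30 for snoRNA hosts and −1.46 for bone and cartilage markers. The medians of the smooth muscle list (0.30), IGF axis (0.31), ribosomal proteins (0.16) and microRNA hosts (0.57) changed sign when mitochondrially encoded genes were left out of the totals, to −0.31, −0.30, −0.45 and −0.03. The adipocyte list had 3 measured members and the endothelial and immune list 4, too few for a median. The median over 15491 genes was 0.24 on total counts and moved by −0.38 with TMM and by −0.61 without mitochondrially encoded genes.

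**Figure D3:**
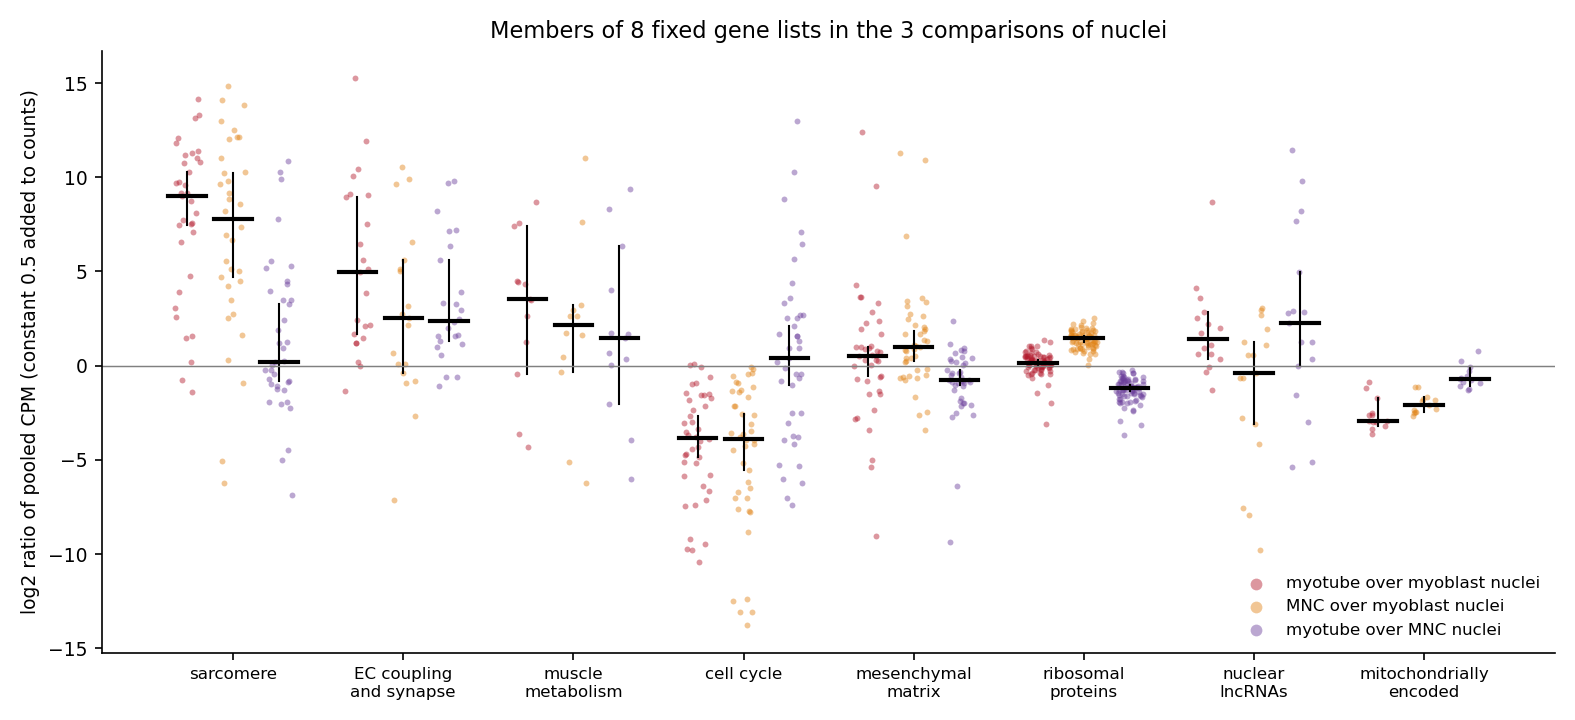
Log2 ratio of pooled CPM (constant 0.5 added to counts) for the measured members of 8 fixed gene lists in the 3 comparisons of nuclei, one point per gene; the horizontal line is the list median and the vertical line its 95% order-statistic interval. Sarcomere medians were 8.99 for myotube over myoblast nuclei and 7.77 for MNC over myoblast nuclei, and cell cycle medians −3.85 and −3.87. MNC nucleus replicate 20 held 70.9% of the sarcomere reads of the MNC nuclei. Median numbers of sarcomere genes with a read at equal depth were 2 in MNC, 4.5 in myoblast and 15 in myotube nuclei. The signs of the mesenchymal matrix and ribosomal medians of myotube over myoblast nuclei depended on the scaling. So did those of the sarcomere and cell cycle medians of myotube over MNC nuclei.

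MNC nuclei were compared with myoblast nuclei, which shows the RNA of cells kept in differentiation medium that remained mononucleated. Most cell cycle genes were lower in MNC nuclei. At equal depth, 5 of 34 MNC nuclei had more sarcomere genes with a read than any of the 48 myoblast nuclei, and the group's sarcomere reads came mainly from 1 nucleus. The Notch receptor NOTCH3, its target HEYL and the differentiation inhibitor ID3 were higher in MNC nuclei than in myoblast nuclei.

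Cell cycle genes had a median of −3.87 (−5.54 to −2.56), or −3.95 relative to all genes, with 35 of 42 at least 2-fold lower, none at least 2-fold higher and each in a smaller share of nuclei. Without MNC nucleus replicates 22, 37 and 39, which at equal depth had reads of 29, 25 and 14 cell cycle genes, the median was −6.93. No read was found in 35 MNC nuclei for the mitotic kinesin KIF2C (at least 4140-fold lower), for GTSE1 (at least 3450-fold) or for the mitotic kinase AURKB (at least 3210-fold), which had reads in 48, 48 and 44 of 54 myoblast nuclei. MKI67 had reads in 4 of 35 MNC nuclei at 21.1 CPM and was 22.6-fold lower (21.4 to 23.8), and its level was 11.9 CPM without MNC nucleus replicate 37. At equal depth, 30 of 34 MNC nuclei (88.2%, 72.6% to 96.7%) had fewer cell cycle genes with a read than any of the 48 myoblast nuclei. RB1, the retinoblastoma protein that restrains entry into S phase, was 6.48-fold higher (5.99 to 7.03), with reads in 19 of 35 MNC nuclei and 32 of 54 myoblast nuclei. The cell cycle exit list went both ways, with 5 of 12 at least 2-fold higher and 3 lower and a median of 0.27 (−2.37 to 2.48).

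Sarcomere genes had a median of 7.77 (4.68 to 10.21; 5.30 with genes at their floor) with 30 of 34 at least 2-fold higher in MNC nuclei. MNC nucleus replicate 20 held 70.9% of the group's sarcomere reads, and without the most-read library of each group the median was 5.52 (2.61 to 8.21). TNNT1 had reads in 3 of 35 MNC nuclei, at 287 CPM and at 10.6 CPM without replicate 20. MYH3 also had reads in 3 of 35, at 140 CPM and at 22.5 CPM without replicate 20. MYOG had reads in 2 of 35 MNC nuclei (5.71%, 0.70% to 19.2%), at 39.0 CPM and at 2.28 CPM without MNC nucleus replicate 43, which held 94.3% of its reads. The 5 nuclei with more sarcomere genes than any myoblast nucleus were replicates 20, 22, 37, 39 and 43. Replicates 22, 37 and 39 also had numbers of cell cycle genes within the range of the myoblast nuclei (11 to 41) and the most genes with a read among MNC nuclei (6225, 6569 and 5751). Without these 3 the sarcomere median was 8.05. At equal depth the median number of sarcomere genes with a read, of 47, was 2 in MNC nuclei and 4.5 in myoblast nuclei, and 10 of 34 MNC nuclei had fewer than any myoblast nucleus.

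Of the mesenchymal matrix genes, 20 of 41 were at least 2-fold higher in MNC nuclei, 17 were within 2-fold and 4 were lower, with a median of 0.98 (0.22 to 1.83). When mitochondrially encoded genes were left out of the totals, 16 were at least 2-fold higher and 10 lower, with a median of 0.43. At equal depth 29 of them had reads in a smaller share of MNC nuclei and 10 in a larger one. The median number of matrix genes with a read was 25 in MNC nuclei and 30 in myoblast nuclei. Over all genes the median number with a read at that depth was 3258 and 4908.5, so fewer genes at large were found in MNC nuclei. COL1A1 stood at 8191 CPM, 4.18-fold higher (4.14 to 4.21), with reads in 34 of 35 nuclei. APOE had reads in 26 of 35 MNC nuclei (74.3%, 56.7% to 87.5%) and was at least 4450-fold higher. CYP1B1, a steroid and xenobiotic hydroxylase, had reads in 22 of 35 and was at least 2290-fold higher, and the hyaluronan-binding protein TNFAIP6 had reads in 16 of 35 and was at least 3690-fold higher, at 336 CPM and 220.4 CPM without MNC nucleus replicate 10. ACTA2, the smooth muscle actin, stood at 546.5 CPM with reads in 14 of 35 MNC nuclei and at 12.5 CPM with reads in 17 of 54 myoblast nuclei, 43.6-fold higher (39.6 to 48.1). The smooth muscle list had a median of 1.14, with 5 of 8 at least 2-fold higher and 1 lower (3 and 1, with a median of 0.59, without mitochondrially encoded genes in the totals).

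Inhibitors of myogenesis had a median of 2.44 (0.23 to 4.60), with 12 of 17 at least 2-fold higher and 2 lower in MNC nuclei on total counts. Leaving mitochondrially encoded genes out of the totals moved the median over all genes by −0.55, so these counts depend on the scaling. At equal depth 8 of the 17 had reads in a larger share of MNC nuclei and 9 in a smaller one. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794), which sequesters the partners of MYOD1 and related factors, stood at 723 CPM (717 to 730) with reads in 30 of 35 MNC nuclei and at 95.3 CPM with reads in 52 of 54 myoblast nuclei, 7.59-fold higher (7.32 to 7.87). NOTCH3 had reads in 27 of 35 MNC nuclei at 374 CPM, 113-fold higher (93.8 to 138), and its level in myoblast nuclei was 0.0616 CPM without myoblast nucleus replicate 9. HEYL, a transcriptional repressor induced by Notch, had reads in 21 of 35 MNC nuclei at 204 CPM, and at 112 CPM without MNC nucleus replicate 38, against 8.39 CPM in myoblast nuclei. BHLHE40, a repressor of the circadian system, had reads in 12 of 35 MNC nuclei at 20.3 CPM and in 1 of 54 myoblast nuclei. MYF5 had reads in 13 of 35 MNC nuclei at 200 CPM, and at 126 CPM without MNC nucleus replicate 47, against 73.6 CPM with reads in 48 of 54 myoblast nuclei.

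Of the ribosomal protein messages, 61 of 78 were at least 2-fold higher in MNC nuclei and none was at least 2-fold lower, with a median of 1.46 (1.26 to 1.55). RPS27 was 5.72-fold higher. When mitochondrially encoded genes were left out of the totals, 29 of the 78 were at least 2-fold higher and none was at least 2-fold lower, with a median of 0.91. Abundant cytosolic messages had a median of 0.95, with 12 of 25 at least 2-fold higher and none at least 2-fold lower (8 and a median of 0.40 with those totals), and FTH1 was 30.2-fold higher (29.4 to 31.1). Early response and stress genes had a median of 1.19 (0.17 to 3.31), with 9 of 18 at least 2-fold higher and 1 lower (7 and 3 with those totals). Mitochondrially encoded genes made up 7.983% of counts in MNC nuclei, and each of the 13 was at least 2-fold lower than in myoblast nuclei. MIR503HG had reads in 1 of 35 MNC nuclei and 49 of 54 myoblast nuclei, 779-fold lower (446 to 1510), and none in MNC nuclei without replicate 47.

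The median over 14941 genes was 0.08 on total counts and moved by −0.58 without mitochondrially encoded genes and the 20 genes with the most reads, with which the medians of fusion and adhesion (0.53), cell cycle exit (0.27), quiescence and reserve cells (0.50) and the IGF axis (0.57) turned to −0.05, −0.31, −0.09 and −0.02. In the subset of libraries in the authors' smaller tables the sarcomere median was 0.62 over 14 measured genes and the cell cycle median −9.81. That subset lacks MNC nucleus replicates 20, 22, 37, 39 and 43, the 5 with more sarcomere genes than any myoblast nucleus.

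Myotube nuclei were compared with MNC nuclei, which share the medium and the time in culture. The groups differ in whether the cell had fused, but also in depth and in how many nuclei had reads of MYOG and sarcomere genes. The comparison therefore does not isolate fusion. Sarcomere genes were found in more myotube nuclei than MNC nuclei, while their pooled levels went both ways with MNC nucleus replicate 20 included. Most genes of excitation-contraction coupling and the synapse and the lncRNA MALAT1 were higher in myotube nuclei. The inhibitor ID3 and the majority of ribosomal protein messages and of abundant cytosolic messages were at least 2-fold higher in MNC nuclei.

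Of the 38 measured sarcomere genes, 34 had reads in a larger share of myotube nuclei. At equal depth the median number with a read was 15 of 47 in myotube nuclei and 2 in MNC nuclei, and 28 of 34 MNC nuclei (82.4%, 65.5% to 93.2%) had fewer than any myotube nucleus. By pooled level 17 were at least 2-fold higher in myotube nuclei and 10 lower, with a median of 0.21 (−0.83 to 3.29) that turned to −0.19 with TMM. Without the most-read library of each group, which is MNC nucleus replicate 20 and myotube nucleus replicate 4, the median was 3.47 (2.35 to 4.46). TNNI1 had reads in 39 of 44 myotube nuclei and 6 of 35 MNC nuclei, at 327 CPM and 142.5 CPM (75.2 CPM without MNC nucleus replicate 43). Coupling and synapse genes had a median of 2.38 (1.31 to 5.59), with 19 of 24 at least 2-fold higher. RYR1 had reads in 36 of 44 and 4 of 35 nuclei, at 695 CPM and 14.4 CPM (3.69 CPM without MNC nucleus replicate 43).

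**Figure D4:**
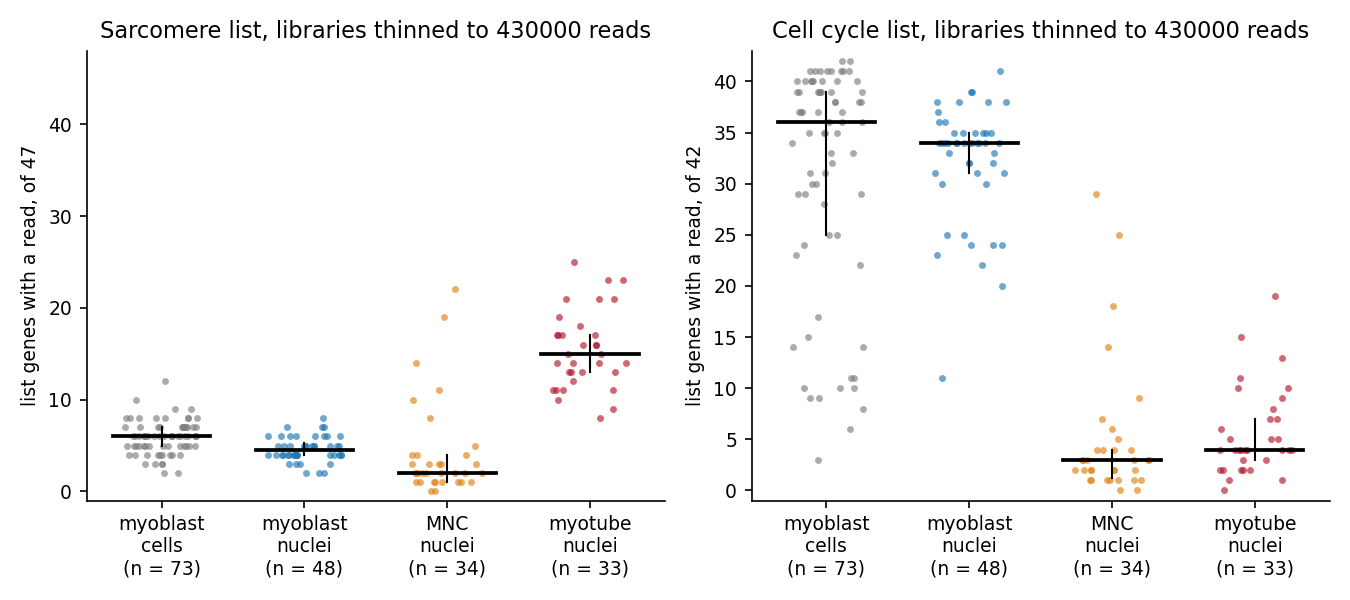
Number of sarcomere genes (of 47, left) and cell cycle genes (of 42, right) with a read per library after thinning to 430000 reads, one point per library, for 73 myoblast cells, 48 myoblast nuclei, 34 MNC nuclei and 33 myotube nuclei; the horizontal line is the median and the vertical line spans the quartiles. Median sarcomere genes were 6, 4.5, 2 and 15, and median cell cycle genes 36, 34, 3 and 4.

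MYOG had reads in 24 of 44 myotube nuclei and 2 of 35 MNC nuclei, although MNC libraries were deeper. ITGA7, which pairs with the beta 1 integrin on muscle cells, stood at 335 CPM with reads in 38 of 44 myotube nuclei and at 16.5 CPM with reads in 12 of 35 MNC nuclei (7.05 CPM without MNC nucleus replicate 37), 20.3-fold higher (19.1 to 21.6). CDKN1C was 10.3-fold higher in myotube nuclei, with reads in 24 of 44 and 5 of 35 nuclei, at 6.58 CPM in MNC nuclei and 3.86 CPM without MNC nucleus replicate 22. MUC1, a cell surface mucin, had reads in 12 of 44 myotube nuclei and none of 35 MNC nuclei, at least 1770-fold higher. Nuclear lncRNAs had a median of 2.27 (−0.04 to 4.96), with 11 of 17 at least 2-fold higher in myotube nuclei and 4 lower, and MALAT1 was 4.82-fold higher. The lncRNA share was 6.314% in MNC nuclei, and that of myotube nuclei was 3.18-fold higher.

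ID3 stood at 29.7 CPM (27.6 to 32.0) with reads in 12 of 44 myotube nuclei (27.3%, 15.0% to 42.8%), 24.3-fold lower (22.6 to 26.3) than in MNC nuclei, where 30 of 35 had reads at 723 CPM. Matrix genes had a median of −0.77 (−1.02 to −0.22), with 14 of 41 at least 2-fold lower, 25 within 2-fold and 2 higher, or −0.99 relative to all genes. Together they made up 3.833% of counts in myotube nuclei and 3.823% in MNC nuclei. COL1A1 was 1.74-fold higher in myotube nuclei. Ribosomal protein messages had a median of −1.18 (−1.35 to −1.01), with 49 of 78 at least 2-fold lower and none at least 2-fold higher. Abundant cytosolic messages had a median of −1.41, with 17 of 25 at least 2-fold lower. ACTB, the cytoplasmic actin, was 7.61-fold lower (7.50 to 7.73) and the glycolytic enzyme PGK1 32.7-fold lower (27.6 to 39.2).

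Cell cycle genes went both ways, with 18 of 41 at least 2-fold higher in myotube nuclei and 14 lower, and their median of 0.39 (−1.05 to 2.13) turned to −0.01 with TMM and was 2.57 (0.78 to 4.86) without MNC nucleus replicates 22, 37 and 39. NUF2 had no read in either group. The other medians were −1.08 for fusion and adhesion, 1.49 for muscle metabolism, −1.06 for smooth muscle, −1.19 for early response and stress and −0.71 for mitochondrially encoded genes. The median over 15048 genes was 0.22 on total counts and moved by −0.40 with TMM, with which the medians of myogenic regulators (0.25), inhibitors of myogenesis (0.05), cell cycle exit (0.02) and quiescence and reserve cells (0.23) turned to −0.15, −0.35, −0.38 and −0.18. Of the endothelial and immune markers, 5 were measured, with a median of 3.10, and they made up at most 0.0017% of counts in any of the 4 groups.

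Nuclei of each stage were compared with one another to describe how alike they were. Across 9089 genes at equal depth, the median Spearman correlation between 2 nuclei was 0.33 for myoblast nuclei (SD over 1128 pairs 0.043), 0.28 for MNC nuclei (SD over 561 pairs 0.053) and 0.22 for myotube nuclei (SD over 528 pairs 0.032). The order of these medians is also that of the median number of genes with a read at equal depth (4908.5, 3258 and 2815). A difference in likeness between nuclei therefore cannot be told apart from a difference in the number of genes detected. Genes are not independent replicates, and pairs share nuclei, so the correlations describe the groups and were not tested.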

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

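Of the alternatives tried, 39 values came from alternatives chosen after the data were seen, which are the totals without mitochondrially encoded genes alone, the filter on libraries by mitochondrially encoded share, the removal of the 3 CH507-513H4 genes and the removal of MNC nucleus replicates 22, 37 and 39. For 19 results, 217 alternative values were computed, of which 186 lay within the interval of the reported value and 31 lay outside it. Of the called values, 0 changed sign, but a sign change could be called only for list medians and share ratios whose reported interval excludes 0. For correlations the interval was the median plus or minus 1 SD over pairs. The MYOG share of myoblast nuclei, none of which had a read, was 0 in each of its 6 alternatives. The log2 ratio of lncRNA shares (1.41) was 1.375 with libraries weighted equally, 1.238 with TPM, 1.398 after thinning, 1.116 without the 20 genes with the most reads, 1.417 without the most-read libraries, 1.634 in the smaller tables, 1.52 after the mitochondrial filter and 0.7318 without the CH507-513H4 genes. The log2 ratio of mitochondrially encoded shares (3.02) was 2.806 with equal weights, 2.555 with TPM, 3.112 after thinning, 3.096 over protein-coding counts, 3.001 without the most-read libraries, 3.119 in the smaller tables and 2.996 after the mitochondrial filter. These intervals are narrow because they count reads only. The ribosomal median in nuclei over cells was −1.16 without mitochondrially encoded and top genes, −1.223 without mitochondrially encoded genes and −1.552 in the smaller tables. The sarcomere median was 6.425 in myotube over myoblast nuclei with a constant of 5, which by construction lowers ratios against 0. In MNC over myoblast nuclei it was 0.6193 in the smaller tables and 4.657 after the mitochondrial filter. In myotube over MNC nuclei it was 3.549 with libraries of at least 2000 genes, 3.465 without the most-read libraries, 9.49 in the smaller tables and 4.184 after the mitochondrial filter. MNC nucleus replicate 20 is among the libraries removed by each of these last settings. The smaller tables also lack MNC nucleus replicates 22, 37, 39 and 43, the others with more sarcomere genes than any myoblast nucleus. The cell cycle median was −9.809 in MNC over myoblast nuclei and 2.762 in myotube over MNC nuclei in the smaller tables, and −6.932 and 2.569 without MNC nucleus replicates 22, 37 and 39, chosen in part for their cell cycle genes. The matrix median in myotube over MNC nuclei was −1.174 with TMM, and the share of myotube nuclei with MYOG was 38.64% at a threshold of 5 reads. Except where said, the cause was not tested. Over their alternatives, the sarcomere median in myotube over myoblast nuclei ranged from 6.43 to 9.38, the cell cycle median from −4.56 to −3.07 and the nuclear lncRNA median in nuclei over cells from 0.46 to 1.41. The matrix median in myotube over myoblast nuclei ranged from −0.08 to 0.92. In myotube over MNC nuclei the sarcomere median ranged from −0.19 to 9.49 and the cell cycle median from −0.01 to 2.76. None of these 3 medians kept its sign, and the reported interval of each includes 0. The number of nuclei limits the shares with a read, since 0 of 35 MNC nuclei allows a share of up to 8.57%, and depth limits the numbers of genes with a read, for which 11 myotube nuclei were too shallow to be compared. No paired analysis was possible because the replicate numbers in the titles only number the wells of a group, and no test between groups was made.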

Other observations

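Genes in this and the next paragraph were chosen after their values were seen, and so were the tests of kept mitochondria, of carried cytoplasm, of a myotube-type nucleus and of the mitochondrial totals; the tests of depth were written before. Nuclei of both differentiated groups had reads, at equal depth, of several genes that few myoblast nuclei had. EPAS1, a hypoxia-regulated transcription factor, was found in 21 of 33 myotube nuclei, 22 of 34 MNC nuclei and 3 of 48 myoblast nuclei. SCD, a fatty acid desaturase, was found in 25 of 33, 25 of 34 and 9 of 48, and SCG2, a granin, in 23 of 33, 21 of 34 and 3 of 48. COL5A3, a chain of type V collagen, was found in 24 of 33 myotube nuclei, 19 of 34 MNC nuclei and 0 of 48 myoblast nuclei. HHIP, an antagonist of hedgehog ligands, went the other way, with reads in 40 of 48 myoblast nuclei, 1 of 33 myotube nuclei and 0 of 34 MNC nuclei, and PCDH9, a protocadherin, was found in 46 of 48, 5 of 33 and 3 of 34.

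Other genes set myotube nuclei apart from MNC nuclei. F13A1, a subunit of clotting factor XIII, was found in 27 of 33 myotube nuclei and 4 of 34 MNC nuclei. DMD, which codes for dystrophin, was found in 22 of 33 and 2 of 34, and ERBB3, a neuregulin receptor, in 19 of 33 and 1 of 34. The unfolded protein response gene HERPUD1 was found in 6 of 33 myotube nuclei and 26 of 34 MNC nuclei, and the redox protein TXN in 5 of 33 and 29 of 34. In myoblasts, ELN, which codes for elastin, was found in 45 of 48 nuclei and 20 of 73 cells, and PASK, a metabolic kinase, in 31 of 48 and 11 of 73.

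The mitochondrially encoded share was 8.13-fold higher in myoblast nuclei than in myoblast cells, and 54 of 54 nuclei lay above the upper quartile of the cells. Whole cytoplasm carried along with nuclei could bring at most the share of a whole cell, so these values argue against it as the cause. Mitochondria, or their RNA, kept with the nuclei while other cytoplasmic RNA was lost would raise mitochondrial genes and lower ribosomal protein messages. The 13 of 13 genes at least 2-fold higher and the ribosomal median of −1.83 were known before this explanation was put, so they do not test it, and it stays open. No biological explanation was tested, since the stage is the same in both preparations.

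MNC nucleus replicate 20 held 70.9% of the sarcomere reads of its group. It was also the group's most-read library, and it held 52.6% after all 34 libraries were thinned to one depth. Depth therefore does not account for all of this, though it can account for part. The values go both ways for a nucleus of myotube type among the MNC nuclei. The library had reads of 22 of 47 sarcomere genes at that depth and an lncRNA share of 13.1%, both within the range of the myotube nuclei, but reads of 5 matrix genes, against 15 to 33 in myotube nuclei, and a mitochondrially encoded share of 0.0475%, against at least 0.558%. Only 1505 genes had a read in that library at full depth, rank 33 of the 35 MNC nuclei, which can limit the matrix genes found. A nucleus of myotube type stays open, as does an unfused cell that had differentiated.

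Ribosomal protein messages were higher in MNC nuclei than in myoblast and myotube nuclei. The median log2 ratio was 1.391 over myoblast and 1.304 over myotube nuclei after thinning, which argues only against a larger weight of deeper libraries. Random thinning leaves the expected share of a gene within a library as it was, so other effects of depth were not tested. It was 0.9114 and 1.231 with totals that leave out mitochondrially encoded genes, which argues against mitochondrial reads as the whole cause. Abundant cytosolic messages had medians of 0.9547 over myoblast and 1.412 over myotube nuclei. The first lay at percentile 55.21 of the random lists, so genes of like expression moved as much. In myotube over MNC nuclei that list lay at percentile 0.115. Cytoplasmic RNA carried along with MNC nuclei may add to the ribosomal difference. It cannot be told apart from a difference of stage, because the series holds no whole MNCs. A difference between preparations is confounded with stage in the same way, since the labels name no separate preparation.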
